A study of Arabidopsis thaliana with 12 samples.

How the data were processed

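The series compared Arabidopsis thaliana of the Columbia 0 ecotype, wild type, after 2 treatments. Per the labels, 6 samples were kept in water for 8 h, and 6 samples were kept in water for 4 h and then in 25 mM ascorbate at pH 5.5 for 4 h. Total RNA of each sample was read in 1 channel of an expression array. The labels number the samples 1 to 6 within each group. They do not say whether the 6 numbers of a group are separate plants, separate hybridisations or repeat readings of one RNA, so the p-values given here measure only the spread between these samples, which may be technical.

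The deposited values were probe intensities on a linear scale, 1 value per probe and array for 3439 probes. The scanner, the background correction and the scaling are not given in the sources used here. No deposited intensity was negative, and 11.5% to 14.2% of the probes on each array were listed at exactly 0. The brightest probe stood at 100 on 9 arrays, 4 of which had 2 probes at 100, and between 85.3 and 91.6 on the other 3 arrays, so the upper end of the scale is relative and may have been capped. The median deposited intensity per array lay between 0.252 and 0.485. It was lowest on ascorbate arrays 1 and 2, at 0.252 and 0.259, against 0.383 to 0.485 on the other 10 arrays. The number of arrays limits the precision of each value.

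From the deposited intensities, every value at or under the 1st percentile of the positive values of its array, zeros included, was raised to that percentile, and log2 was taken. This floor lay between 0.0075 and 0.0545 on the 12 arrays. Array medians of log2 differed by up to 0.94, over the limit of 0.3 set in advance, so the arrays were quantile normalized in limma. All values at the floor then shared 1 log2 level of -5.92, and differences between values at the floor have no meaning. The 173 probes at 0 on all 12 arrays were left out of the tests, a choice made after the values were seen, which left 3266 probes. Ascorbate was compared with water for each probe with lmFit and eBayes of limma 3.58.1 in R 4.3.3, default settings, two-sided, with Benjamini-Hochberg adjustment over the 3266 probes and a threshold of 0.05. Fold changes are ascorbate against water on the normalized log2 scale, and errors of fold changes are standard errors of that fit.

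A table of platform annotation gave 1 gene for 692 probes, several genes for 870 and none for 1877. Only probes with 1 gene were named. For 690 of the 692 a locus was found in the RefSeq gene table of assembly TAIR10.1, which served for names only. No genome build was named for the array, so no coordinates are given. Before the data were examined, 24 gene lists with 442 loci were fixed. They covered ascorbate synthesis and recycling, superoxide dismutases and catalases, thiol peroxidases and thioredoxins, photosynthesis, photorespiration, plastid gene expression, ribosomes, chaperones and import, pigments and isoprenoids, starch, sulfur and nitrogen, fatty acids, jasmonate, phenylpropanoids, stress markers, markers of roots and senescence, and cytosolic housekeeping genes. Lists with 4 or more measured members were tested with camera, preset correlation 0.01, and with fry, on the brightest probe of each locus.

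The genes named in the report were also chosen by a rule fixed in advance. The rule took the 10 highest and 10 lowest fold changes among single-gene probes past the threshold whose 6 ascorbate values all lay on 1 side of the water mean. It also took the 2 members with the smallest p of each tested list. It further took passing members of the lists of ascorbate recycling, ascorbate synthesis and superoxide dismutase or catalase, and a set of antioxidant genes of which PRXIIE and GLDH were measured. Genes named outside this rule are said to be so.

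Whether replicate numbers pair the samples was checked on deviations from the group means, across all tested probes. The same number in water and ascorbate correlated at 0.35, 0.36, 0.56, 0.56, 0.53 and 0.53 for numbers 1 to 6, and all 12 samples correlated best with their own number in the other group. By the limit of 0.1 set in advance, the numbers pair the samples, and the pairing comes from the numbers in the labels. Within a group, all 12 samples correlated best with the consecutive number, 1 with 2, 3 with 4 and 5 with 6. Those correlations were 0.24, 0.19 and 0.73 in water and 0.088, 0.30 and 0.74 in ascorbate, and the consensus correlation of consecutive numbers over all probes in limma was 0.697. Averaging consecutive numbers had been planned as the main analysis only if all 6 of these passed a limit that 4 of them missed, so the 6 against 6 comparison stayed the main one. That comparison had been fixed in advance without a block for the number. Its p-values therefore leave out the pairing of water and ascorbate by number, and the fit with that block is an alternative.

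The method was tested on simulated data with the spread of the 3266 real probes, in 10 simulations per case. With 200 changed probes and independent samples, the 6 against 6 comparison recovered 61.4% of changes of 1 log2 unit and 19.7% of changes of 0.5 log2 units, and with no change it called 0.1 probes on average. Averaging consecutive numbers of those independent samples called 35.6 probes and recovered 31.2% and 1.8%, against 85.7 probes called without averaging. With consecutive numbers correlated at 0.7, near the 0.697 of the real samples, the 6 against 6 comparison called 31.8 probes where nothing had changed. When 200 probes had changed, 96 of its 202.4 calls were false. With the correlation of 0.7, averaging consecutive numbers gave 0 false calls and recovered 0% of the changes. The simulations left out the correlation of the same number in water and ascorbate, 0.35 to 0.56 in the real samples. They also gave 0.7 to every pair, while the real correlations of consecutive numbers ran from 0.088 to 0.74. The share of false calls therefore cannot be carried over to the real comparison.

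The alternatives were no normalization, centring on array medians, other treatments of low values, a filter on dim probes, another variance model, an exact rank-sum permutation test over all 924 splits, the replicate number as a block, averaging or blocking of pairs of numbers, and leaving out numbers, samples and pairs. Centring on housekeeping genes was not run because no member of that list was measured. No value column was left unused.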

Results

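Total RNA of wild-type Arabidopsis, ecotype Columbia 0, was profiled on 12 one-channel expression arrays. In 6 samples the plant material had been in water for 8 h, and in the other 6 it had been in water for 4 h and then in 25 mM ascorbate at pH 5.5 for 4 h. Ascorbate, or vitamin C, is the main water-soluble antioxidant of plant cells. The comparison asks which transcripts differ after 4 h of supplied ascorbate, within a total time of 8 h that was the same in both groups. The labels give no pH for the water and name no control moved to a solution without ascorbate. Effects of ascorbate, of the pH, of the solute load and of the change of solution therefore cannot be told apart here. Summed deposited intensity per array ranged from 3054 to 3562.

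**Figure D1:**
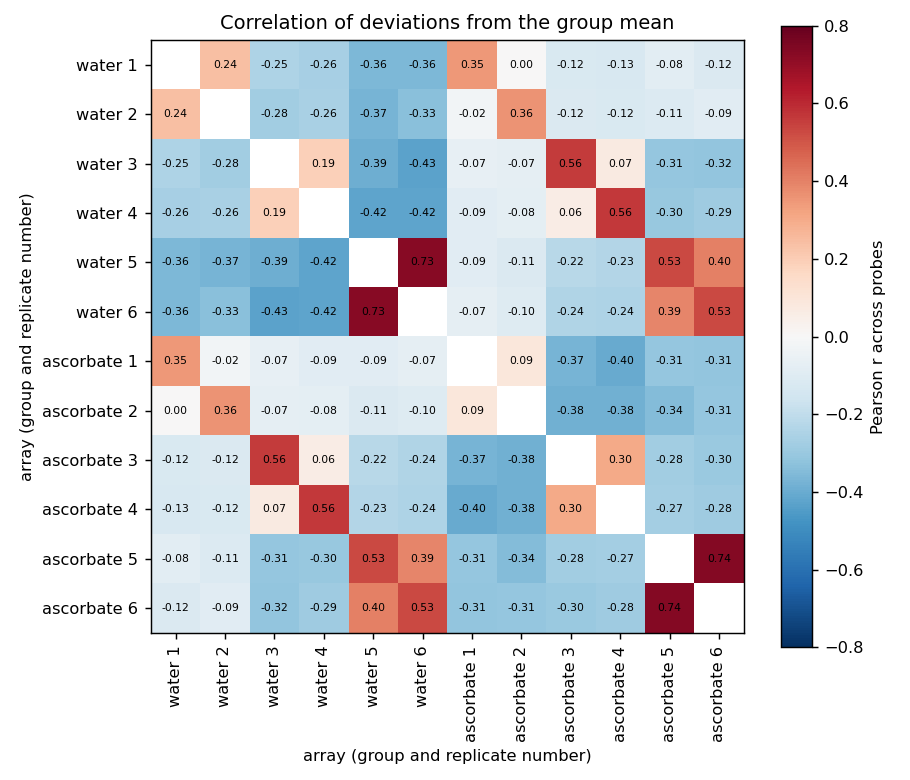
Pearson correlation across probes of each array's deviation from its group mean, for all pairs of the 12 arrays, both axes listing arrays by group and replicate number; colour and printed value give r. Arrays of the same number in the 2 groups correlated at 0.35 to 0.56, and consecutive numbers of a group at 0.09 to 0.74.

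Between the ascorbate and water groups, 559 of the 3266 tested probes (17.1%) differed, of which 318 were higher and 241 lower in ascorbate. Among the 120 changed probes with a single gene, 72 were higher and 48 lower. Genes that rose included TPP2 (tripeptidyl peptidase II), the MYB-like factor AT5G52660 and the kinesin AT3G44050, and genes that fell included the protein phosphatase 2C AT4G33500, the calmodulin-binding protein gene iqd32 and the RNA-binding protein gene UBA1A. Of these, AT5G52660 lost its call in 21 of 37 alternatives and iqd32 in 17 of 38, the others in 2 to 5. Most changes were modest, with a median absolute log2 fold change of 0.72, and 123 probes changed by at least 2-fold, 66 up and 57 down. The 2 groups did not overlap at all for 315 of the 3266 tested probes, where chance gives 0.22% of probes if the 6 samples of a group are independent. Unadjusted p was under 0.05 for 1006 probes.

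The calls rest on treating the 6 samples of a group as separate. With consecutive numbers averaged, 3 against 3, limma called 1 probe, lower by 3.10 on the log2 scale and with no gene in the annotation, although 501 probes had an unadjusted p under 0.05 against 163.3 from chance alone. Averaging with a block for the averaged pair called 0 probes, with 625 at an unadjusted p under 0.05, and a random block for the pairs called 148. With numbers 1 and 4, 2 and 5, and 3 and 6 averaged instead, also 3 against 3, 479 probes passed, 257 higher and 222 lower, and 219 with a block for the averaged numbers. The fall to 1 thus depends on which numbers are averaged. Each of these other averages mixes 2 of the correlated pairs, so differences between pairs partly cancel and the spread shrinks. The 479 therefore cannot show what fewer values per group cost by themselves. The other way round, a fixed block for the pairs called 983. The replicate number as a block, which takes up the pairing of the samples by number, called 796, of which 500 were shared with the fit without it. The share of calls that were higher, 56.9%, was 21.7% on the intensities as deposited and 72.7% with each array centred on its median. The median fold change of all tested probes was 0.001 on the log2 scale after quantile normalization, -0.35 as deposited and 0.04 after centring.

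**Figure D2:**
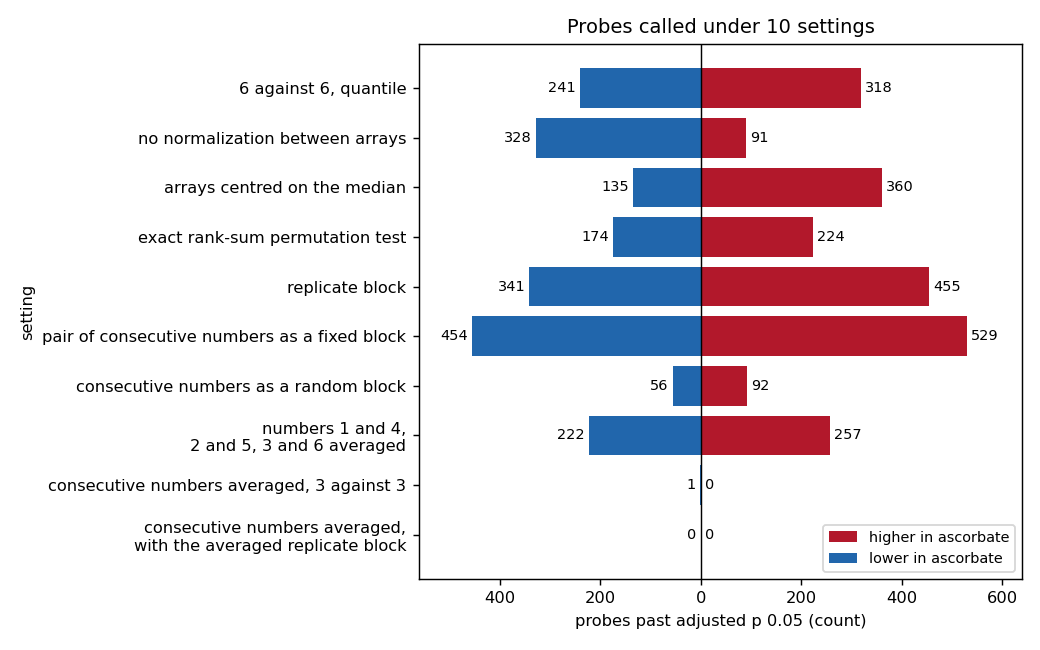
Number of probes past an adjusted p of 0.05 under 10 settings; bars to the right count probes higher in ascorbate and bars to the left probes lower in ascorbate. The first setting called 318 higher and 241 lower, and averaging consecutive numbers left 0 higher and 1 lower.

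Of the 3266 tested probes, 1377 (42.2%) had the same direction in all 3 pairs of numbers, against 25% with independent signs. Across the 2711 probes above 0 on all arrays, fold changes of the pairs correlated at 0.34 for 1 and 2 with 3 and 4, 0.49 for 1 and 2 with 5 and 6, and 0.48 for 3 and 4 with 5 and 6. These are correlations across probes, which are not independent replicates. In numbers 1 and 2, 221 of those probes were at least 2-fold higher and 204 lower, in 3 and 4 the counts were 69 and 89, and in 5 and 6 they were 130 and 124. Of the changed probes above 0 on all arrays, 25 differed by at least 2-fold in the same direction in every pair, 19 higher and 6 lower. The single-gene probes among these 25 were TPP2, AT1G11470 and AT4G33500. All pair values here are on the normalized scale. In numbers 1 and 2 as deposited, AT1G11470 was at 0.0832 and 0.130 in water and 0.0774 and 0.159 in ascorbate. TPP2 was at 0.141 and 0.0943 in water and 0.179 and 0.184 in ascorbate, both under 2-fold. AT4G33500 was at 1.17 and 1.14 in water and 0.194 and 0.181 in ascorbate.

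TPP2, which encodes a large cytosolic peptidase, rose from -3.34 ± 0.52 to -1.85 ± 0.31 log2 intensity (SD, n = 6 each), 2.82-fold, with a log2 fold change of 1.50 ± 0.24 (SE, limma adjusted p 0.0021). AT1G11470 rose 2.51-fold (log2 1.33 ± 0.26 SE, limma adjusted p 0.0065), but its value was 0.56 with an adjusted p of 0.25 on intensities as deposited. AT3G44020 rose 2.19-fold with the smallest p of the 20 genes named for size (log2 1.13 ± 0.10 SE, limma adjusted p 8.0e-05), from -0.65 ± 0.13 to 0.49 ± 0.18 (SD, n = 6 each). AT2G15440 behaved in the same range, at 1.06 ± 0.10 (SE, limma adjusted p 0.00015). AT3G44050, a kinesin motor protein gene, rose by 1.09 ± 0.17 on the log2 scale (SE). In all of these except AT1G11470 the adjusted p stayed under 0.05 as deposited and after centring, but TPP2 was smaller as deposited, at 0.83 (adjusted p 0.029).

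AT1G67820, of the protein phosphatase 2C family, rose by 1.04 ± 0.15 log2 units (SE), and AT2G42490, a copper amine oxidase gene, by 1.05 ± 0.22. AT4G39230, an isoflavone reductase-like gene, rose by 1.08 ± 0.27. For these 3 the change on deposited intensities was 0.39, 0.50 and 0.46 and did not pass, with adjusted p of 0.34, 0.15 and 0.30. In numbers 1 and 2, deposited AT1G67820 was lower in ascorbate, at 0.108 and 0.124 against 0.187 and 0.174 in water. Its rise of 0.60 log2 units in that pair thus arose in the normalization. In numbers 3 to 6 it was higher in ascorbate as deposited too. AT5G52660, a MYB-like transcription factor gene, rose by 1.52 ± 0.42, led by numbers 1 and 2 at 2.71 against 0.81 and 1.02 in the other pairs. In numbers 5 and 6 AT5G52660 was nearly the same as deposited, at 0.0917 and 0.0893 in water and 0.0930 and 0.0903 in ascorbate. The gene's 1.02 in that pair thus arose in the normalization. Its call was lost without any one of ascorbate samples 1 to 4 or water samples 1, 2, 5 and 6 (1.34 to 1.52, adjusted p 0.051 to 0.070), as deposited (0.45, adjusted p 0.32) and after centring (0.84, adjusted p 0.072). AT4G39230 lost its call without numbers 1, 2 or 5, at 0.97, 0.85 and 1.16. FZL, a dynamin-related protein gene of chloroplast membranes, was dim. It was listed at 0 on water arrays 1 and 2, and at 0.0267, 0.0454, 0.0536 and 0.0522 on water arrays 3 to 6. On ascorbate arrays 1 to 6 it stood at 0.0152, 0.0411, 0.0278, 0.0789, 0.106 and 0.113. After normalization water arrays 1, 2 and 6 were at the floor, so no fold is given (limma adjusted p 0.0032). The log2 difference was 0.43 with the 25th percentile offset (adjusted p 0.0073), and it did not pass as deposited (adjusted p 0.40) or after centring (adjusted p 0.14).

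**Figure D3:**
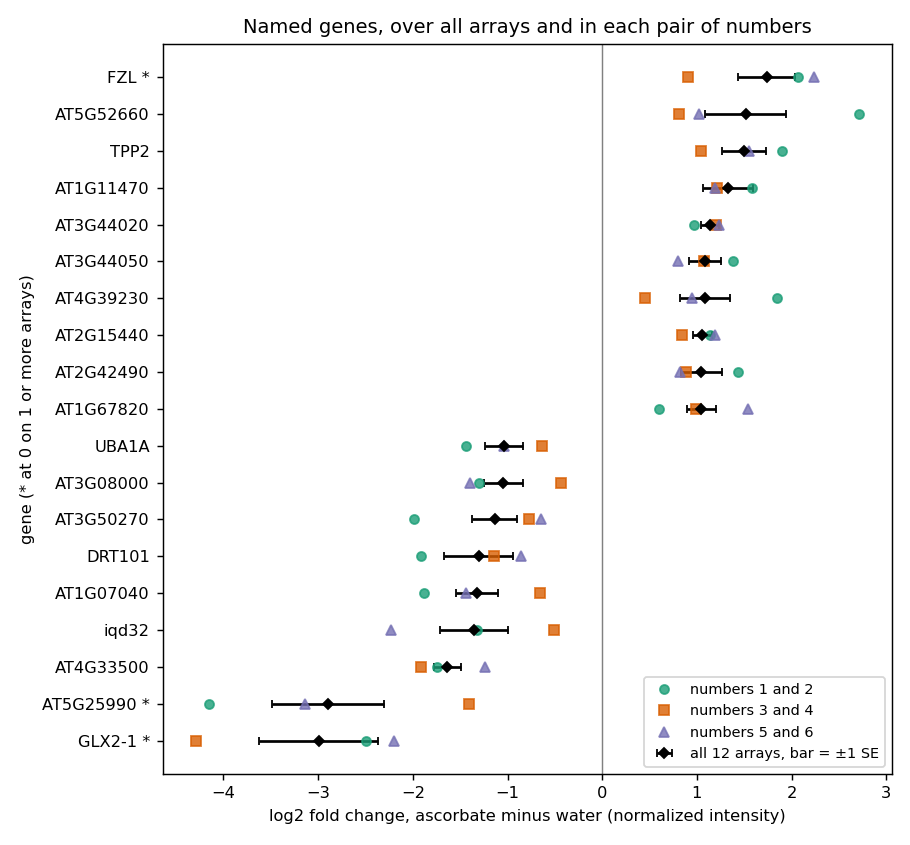
Log2 fold change, ascorbate minus water, of 19 named genes (vertical axis); diamonds are the fit over all 12 arrays with bars of 1 SE, and coloured symbols the change within each pair of numbers, 2 arrays against 2. Values at the floor enter FZL, GLX2-1 and AT5G25990. After normalization all pairs lie on the same side of 0 for each gene, and AT4G33500 lies between -1.92 and -1.24 in the 3 pairs. As deposited, AT1G67820 was lower in ascorbate in numbers 1 and 2, at 0.108 and 0.124 against 0.187 and 0.174 in water.

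Among the genes that fell, AT4G33500, of the protein phosphatase 2C family, went from 0.11 ± 0.06 to -1.53 ± 0.34 log2 intensity (SD, n = 6 each), 3.10-fold lower, with a log2 fold change of -1.63 ± 0.14 (SE, limma adjusted p 9.3e-05). UBA1A, an RNA-binding protein gene, fell by 1.04 ± 0.20 log2 units (SE), AT3G08000, a gene for a protein with an RNA-recognition motif, by 1.04 ± 0.21, and AT1G07040 by 1.32 ± 0.22. AT3G50270, of the HXXXD acyltransferase family, fell by 1.14 ± 0.24. The adjusted p of these 4 genes lay between 0.0025 and 0.0083. DRT101 fell by 1.31 ± 0.36 and iqd32 fell by 1.36 ± 0.36, with adjusted p of 0.031 and 0.026. The call of DRT101 was lost as deposited (-1.63, adjusted p 0.056) and after centring (-1.24, adjusted p 0.059). It was also lost without ascorbate sample 1 (-1.20, adjusted p 0.064) or any one of water samples 3 to 6 (-1.32 to -1.26, adjusted p 0.055 to 0.064). The call of iqd32 was lost without ascorbate sample 2 or 6 (-1.17 and -1.29, adjusted p 0.055 and 0.056) or without water sample 2, 3, 5 or 6 (-1.38 to -1.32, adjusted p 0.051 to 0.055).

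A further 3 genes fell to the lower end of the scale. AT2G21530, a forkhead-associated domain protein gene, was listed at 0 on all 6 ascorbate arrays and at 0.323, 0.350, 0.0479, 0.157, 0.446 and 0.362 on water arrays 1 to 6, so no fold is given (limma adjusted p 0.00058). GLX2-1, a glyoxalase II gene, stood at 0.198, 0.343, 0.345, 0.335, 0.588 and 0.651 on water arrays 1 to 6. On ascorbate arrays 1 to 6 it was at 0, 0.0319, 0.00256, 0, 0.116 and 0.181 (limma adjusted p 0.0088). AT5G25990 stood at 0.363, 0.358, 0.405, 0.375, 0.394 and 0.342 on water arrays. It was at 0 on ascorbate arrays 1 and 2 and at 0.0765, 0.221, 0.0860 and 0.0363 on ascorbate arrays 3 to 6 (limma adjusted p 0.0078). The size of these changes depends on how low values are treated. Adding an offset before log2 shrinks fold changes by construction, most for dim probes. With the 25th percentile offset all 20 genes named for size changed less, with a median ratio of 0.518 to the log2 values above, among them TPP2 at 0.75, AT1G11470 at 0.53, AT5G52660 at 0.42, iqd32 at -0.69, AT2G42490 at 0.54, AT1G07040 at -0.86 and AT4G33500 at -1.29. The 20 genes named for size kept their direction in every alternative that gave them a value, and all 20 lost the call when consecutive numbers were averaged, with or without a block.

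Of the 442 loci in the fixed lists, 22 were measured by a single-gene probe. Among these, 1 was higher and 1 lower, adjusted over all probes, and the same number, 2, passed adjusted over the list alone, here the 22 together. With the replicate number as a block, 4 were higher and 1 lower. The 3 added by the block were KAR and FATB of fatty acid synthesis and PSB27 of photosystem II, at 0.31 ± 0.10, 1.46 ± 0.61 and 0.64 ± 0.32 (SE, named after their values were seen). Their adjusted p was 0.0505, 0.13 and 0.20 without the block and 0.034, 0.020 and 0.024 with it, and over all alternatives it ranged from 0.0081 to 0.42, 0.0056 to 0.65 and 0.024 to 0.62. The block was not the only setting in which they passed. After centring KAR was at 0.69 and PSB27 at 1.08 (adjusted p 0.015 and 0.041), KAR passed by the rank-sum test (adjusted p 0.036), and in all they passed in 8 of 38, 3 of 37 and 2 of 38 alternatives. FATB was at 0.83 as deposited. With consecutive numbers averaged and the block, 0 of the 22 passed. The 2 that passed without the block belong to chlorophyll synthesis and are named after their values were seen. CHLP, geranylgeranyl reductase, rose 1.52-fold, from 0.43 ± 0.15 to 1.03 ± 0.12 log2 intensity (SD, n = 6 each, limma adjusted p 0.0012), a log2 fold change of 0.60 that was 1.04 after centring. CHLM, magnesium protoporphyrin methyltransferase, fell by 0.90 ± 0.23 log2 units (SE, limma adjusted p 0.020), with changes of -1.27, -0.21 and -1.21 in the 3 pairs. CHLM lost the call without number 1, 5 or 6 (-0.90, -0.79 and -0.91, adjusted p 0.053, 0.087 and 0.071).

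The plastid ribosome list had 6 measured members, of which 1 was listed at 0 on 5 water and 6 ascorbate arrays and so had no values to compare. None of the other 5 passed, also adjusted over the list alone. Its mean log2 fold change was -0.06 and its median 0.01 (camera p 0.94, direction up, and adjusted p 0.96 with an estimated correlation), so mean and test differed in sign. PRPL17 had a change of 0.13 ± 0.13 (SE, limma adjusted p 0.51), and of -0.13 as deposited. PRPL34 was listed at 0 on 1 water array and 3 ascorbate arrays (limma adjusted p 0.52). Water arrays 1 to 6 read 0.0413, 0, 0.117, 0.121, 0.139 and 0.145, and ascorbate arrays 4 to 6 read 0.0611, 0.102 and 0.125.

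The list of thiol peroxidases and thioredoxins had 4 measured members, and none passed, also adjusted over the list alone. Its mean was 0.02 and its median -0.09 (camera p 0.65, adjusted p 0.94, direction down, and adjusted p 0.96 with an estimated correlation), again with mean and test of opposite sign. By fry the adjusted p was 0.82 for both lists. PRXIIE, a plastid peroxiredoxin, had a change of -0.79 ± 0.29 (SE, limma adjusted p 0.085), with -1.37, 0.18 and -1.18 in the 3 pairs, and of -1.28 as deposited. It passed without ascorbate sample 3 or 4 (-0.97 and -0.95, adjusted p 0.027 and 0.034), without number 3 (-0.99, adjusted p 0.046) and without the pair 3 and 4 (-1.27, adjusted p 0.0059). It also passed with the pairs as a fixed block (adjusted p 0.036) and with numbers 1 and 4, 2 and 5, and 3 and 6 averaged (adjusted p 0.039), but not with the replicate number as a block (adjusted p 0.090). FTRB, a subunit of ferredoxin-thioredoxin reductase, had a change of 1.03 ± 0.55 (SE, limma adjusted p 0.23), but of 0.18 as deposited and 0.57 after centring. GLDH, which carries out the last step of ascorbate synthesis, was the 1 measured member of its list and had a change of -0.52 ± 0.44 (SE, limma adjusted p 0.47), and of -1.05 as deposited and -0.13 without ascorbate sample 2. No member of the lists of ascorbate recycling, or of superoxide dismutases and catalases, was measured by a single-gene probe.

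**Figure D4:**
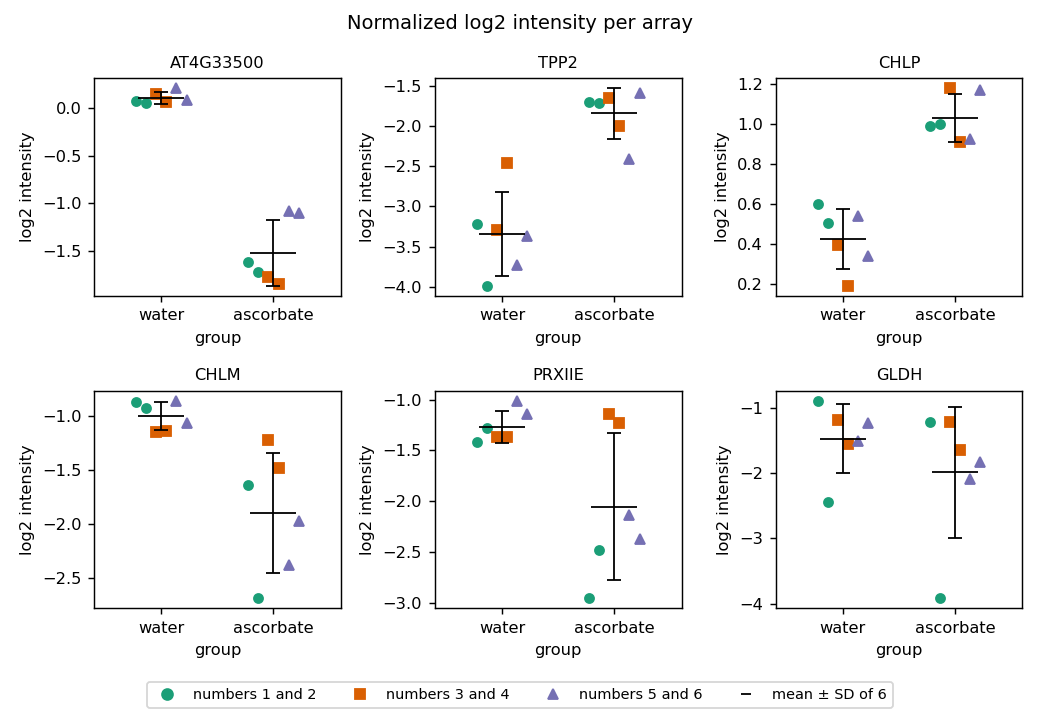
Normalized log2 intensity (vertical axis) of 6 genes on each of the 12 arrays, by group; symbols mark the pairs of numbers, and black lines the mean with the SD of 6 arrays. AT4G33500 and CHLM are lower and TPP2 and CHLP higher in ascorbate without overlap, while PRXIIE and GLDH overlap between groups.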

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

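The tests of repeat samples and of a shared response of the pairs were chosen after the results were seen. The splits of the samples, the loess check and the test of the 2 dim arrays were set before, but the loess check was judged no test after its result was seen.

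In 5 of 76 groups of 6 values, 1 sample lay far from the other 5, where chance gives about 3.8. For iqd32 water sample 1 was at -2.13 log2 intensity against -1.68 to -1.48. For AT3G50270 water sample 2 was at -0.66 against -1.18 to -0.99. For GLDH ascorbate sample 2 was at -3.91 against -2.09 to -1.22. For FATB ascorbate sample 4 was at -3.91 against -2.19 to -1.50. For PSB27 water sample 5 was at 1.41 against -0.20 to 0.36.

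The 6 against 6 comparison called 559 probes. In 100 splits of the 12 samples, 1, the real one, called that many, and the highest other split called 7. Among all 32 splits that part the 2 samples of every number, the real split was again the 1 that called as many, and the highest other called 9. Chance assignment is argued against as the source of the calls only if the samples of a group are independent. The consensus correlation of 0.697 for consecutive numbers goes against that independence. If consecutive numbers are repeats, or separate samples that shared growth or handling, the real split has just 3 others of those 32 that keep them together. Those called 0, 0 and 9, too few splits for a share under 0.05, so chance assignment is then not excluded.

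The calls fell to 1 when consecutive numbers were averaged. A response in 1 pair of numbers alone is argued against, since the lowest correlation of fold changes between pairs was 0.34. Whether an intensity-dependent distortion plays a part was not settled: removing a loess trend moved the correlations by at most 0.010, the lowest to 0.33, so it could not serve as a test. That consecutive numbers are repeats of one RNA or one hybridisation stays open: 12 of 12 samples correlated best with their consecutive number, which is consistent with it. It is equally what shared growth or handling of separate samples could give. With numbers 1 and 4, 2 and 5, and 3 and 6 averaged 479 probes passed, and 219 with a block, so the fall depends on which numbers are averaged. What 3 values per group alone would give cannot be told from this, since each of those averages mixes 2 pairs and differences between pairs partly cancel.

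The split between higher and lower calls turned with the scaling, from 56.9% higher to 21.7% as deposited. The low medians of ascorbate arrays 1 and 2 are a candidate cause, but without numbers 1 and 2 the share as deposited was 38.9% against 55.4% after quantile normalization, so these arrays are not the whole cause. Whether RNA amount, labelling or a true shift of the whole distribution lies behind the rest was not tested. The floor at the 1st percentile was lower in ascorbate in numbers 1 and 2, at 0.0075 and 0.0077 against 0.0179 and 0.0183 in water. It was also lower in 5 and 6, at 0.0202 and 0.0247 against 0.0451 and 0.0545. In 3 and 4 it was 0.0125 and 0.0106 against 0.0116 and 0.0112. What part this low end has in the split was not tested.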

How the results depend on the processing

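Leaving out pairs of numbers, leaving out ascorbate arrays 1 and 2, the fixed block for pairs, deposited values without numbers 1 and 2, and the 2 other choices on probes at 0 were added after the data were seen. The count of 559 moved by over 1.5 times in these settings: 1 with consecutive numbers averaged, 0 with the averaged replicate block, 219 with numbers 1 and 4, 2 and 5, and 3 and 6 averaged with that block, 148 with a random block and 983 with a fixed block. It also moved by over 1.5 times without number 5, without number 6 and without the pair 5 and 6, to 314, 329 and 261. With the replicate number as a replicate block the count was 796, 500 of them shared, which is within 1.5 times, and the block changed no call of the 25 genes named by rule, but ended that of PIFI and added KAR, FATB and PSB27. With numbers 1 and 4, 2 and 5, and 3 and 6 averaged without a block the count was 479. Leaving out samples, numbers or pairs gave 261 to 597, lowest without the pair 5 and 6 (261), and 314 without number 5 and 329 without number 6. Fewer samples are part of those losses, and for the rest the cause was not tested. The other settings gave 375 to 617. The 20 genes named for size reversed in no setting. Their calls were lost for 20 of 20 after averaging consecutive numbers, 12 with the random block, 10 without the pair 5 and 6, 8 with numbers 1 and 4, 2 and 5, and 3 and 6 averaged with the block (2 without it), 7 without the pair 1 and 2, 7 as deposited and 3 after centring, and for 0 with the 25th percentile offset or the trend and robust fit. The offset nevertheless made all 20 changes smaller, 8 of them by over 1.5 times in fold, though adding a positive value before log2 shrinks ratios by construction. PRPL17 reversed to -0.13 as deposited, when the median of all probes was -0.35.

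No list passed in any setting, the lowest adjusted p being 0.54, and means close to 0 changed sign, the cause not tested. The plastid ribosome mean was -0.504 as deposited, -0.111 after centring, 0.0606 with low values missing, 0.0132 with the offset, 0.0831 without the dimmest 25% of probes, 0.0831 with probes above 0 everywhere and 0.0907 without ascorbate arrays 1 and 2. Leaving out samples, numbers or pairs gave -0.147 to 0.0703. The thiol list mean was -0.565 as deposited, -0.173 after centring, -0.0816 with low values missing, -0.0546 with the offset and -0.324 without the dimmest 25%, 0.140 without ascorbate arrays 1 and 2, and -0.119 to 0.120 on leaving out samples, numbers or pairs. Centring on housekeeping genes was not run, as none was measured. Genes near the floor, such as FZL, are limited by signal over background, which is not given.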

Other observations

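The test of photosynthesis genes was chosen after the fold changes were seen. The tests of organelle RNA factors and of probes with shared annotation were set before, though both lists came from the annotation of this array.

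Factors of organelle RNA, proteins with pentatricopeptide repeats and mTERF proteins, formed the most numerous family with single-gene probes that was looked at, with 21 measured members, 1 of them listed at 0 on 6 water and 5 ascorbate arrays. AT3G49740 and AT4G04370, both with pentatricopeptide repeats, fell by 0.76 ± 0.22 and 0.60 ± 0.11 log2 units (SE), and the mTERF gene AT3G46950 rose by 0.43 ± 0.12 (limma adjusted p 0.034, 0.0034 and 0.028, named after their values were seen). Leaving out single samples ended the call of AT3G49740 for ascorbate 1, 2, 5 and 6 and water 3 to 6 (-0.74 to -0.69), and of AT3G46950 for ascorbate 5 and 6 and water 1, 2, 5 and 6 (0.37 to 0.44). AT3G49740 was at -1.38 as deposited. AT4G04370 did not pass after centring (-0.35, adjusted p 0.15), nor AT3G46950 as deposited (0.36, adjusted p 0.15), while after centring it was at 0.75 (adjusted p 0.0035). The mean of the 21 was -0.25 and the median -0.15. AT5G39980 and AT3G13150 had the lowest values, -1.44 and -1.04, each with 1 ascorbate array at 0. AT5G15280, at -0.73, had 3 ascorbate arrays at 0, and none of these genes passed (named after their values were seen). AT5G39980 was at -4.34 in numbers 1 and 2, and at -0.06 and 0.08 in the other pairs. The mean thus rests in part on values at the floor. A joint shift is a hypothesis the data leave open: the camera p against other genes was 0.062, and 0.068 with an estimated correlation, while fry, which does not compare with other genes, gave a p of 0.00029. A p this close to the threshold excludes neither a shift nor its absence.

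Of genes for the photosynthetic NDH complex, 3 were measured, under the 4 needed for the list test, so it was not run. NdhS, a subunit, fell by 0.98 ± 0.17 log2 units (SE, limma adjusted p 0.0032), but the change was -0.29 with an adjusted p of 0.61 after centring and -0.68 with 0.088 as deposited. PIFI, a factor tied to the complex, was at 1.01 ± 0.31 (SE, limma adjusted p 0.048), with an adjusted p of 0.093 with the replicate number as a block. It did not pass in 27 of 38 alternatives, and pairs 1 and 2, 3 and 4, and 5 and 6 gave -0.00084, 0.84 and 2.18. CRR21 had a change of 0.15 ± 0.15. These 3 genes were named after their values were seen.

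The 6 measured genes of photosystems, light harvesting and the Calvin cycle had a mean of 0.12 and a median of 0.12, with camera p 0.68, and none passed in the 6 against 6 comparison. PSB27 passed with the replicate number as a block (0.64, adjusted p 0.024) and after centring (1.08, adjusted p 0.041, named after its value was seen), and with the pairs as a fixed block 1 other gene did (0.25, adjusted p 0.048). With members of both signs, a joint change could not be settled.

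For 53 pairs of probes that carry the same annotated gene or genes, fold changes correlated at 0.51 across pairs (permutation p 0.00017, Spearman rho 0.33, permutation p 0.0146), 1 relation tested. That is consistent with probes of the same genes responding alike, but r was 0.26 without the 2 pairs farthest from the median, so much of it rests on those. In 2 pairs both probes passed, with the same direction. The larger of these, 2 probes annotated to the same several genes, rose by 1.81 and 2.05 log2 units and by at least 2-fold in every pair of numbers. More pairs of probes had just 1 probe past the threshold, with the other going the same way in some and the opposite way in others. With 17.1% of all tested probes called, 2 such double calls do not by themselves argue for a shared response.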
